A study of Homo sapiens with 4 samples.

How the data were processed

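MicroRNA levels were measured in LNCaP cells, an established human prostate adenocarcinoma line that carries an androgen receptor. Per the labels, the cells were grown in flasks and kept for 24 hours in androgen-free medium with 10% charcoal-stripped serum. They then received 0, 0.1, 1 or 10 nM of R1881, a synthetic androgen. Total RNA was extracted with Trizol, and 10 µg was labelled with Cy3 and hybridised to a 1-colour custom CombiMatrix array whose probes covered 474 human miRNAs, per the labels. Each dose has 1 array, so the series has 4 arrays and no replicates. The length of the treatment, the scanner and the image software are not given in the sources used here.

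Each array's table gives 1 mean signal per probe, an intensity on a linear scale that the authors averaged over spots, for 1406 probes. By their names, 455 probes match human miRNAs, 167 mouse, 56 rat, 97 viral and 10 worm miRNAs, 604 are copies with 2 mismatched bases, and 17 are other controls. Per the file headers the column is a mean signal, and no background step or spread between spots is stated. A mismatch probe listed at 0, which occurred for 3 to 7 probes per array, was treated as missing. The authors' value table holds the same intensity minus a constant for each array. That constant equals the array's median mismatch signal, which was 371.5 for the untreated array and 355, 295.75 and 280.25 at 0.1, 1 and 10 nM. Cells are filled only at about 1.5 times that median or more. The column medians of that table were 489, 377.75, 493 and 333.25, and neither a scaling between arrays nor a log step was found in it. Its stated direction, relative to the untreated sample, was not seen in the values, which are levels and not ratios.

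Signals were corrected with normexp at an offset of 50 over all probes in limma 3.58.1 under R 4.3.3, control probes were dropped, and the match probes of all species were quantile normalised over the 4 arrays. Values were then read on the log2 scale for the 455 human miRNAs. An array detected a miRNA when the signal exceeded the median plus 3 scaled median absolute deviations of the mismatch probes. The rule that names negative controls was written before the data were examined, whereas the choice of the mismatch probes as those controls was made once the probe names were seen. The Bio and Lambda spike probes carry the tag neg in their names and were not used for that threshold. A miRNA entered the model fits when at least 1 array detected it, and entered a dose's counts when at least 1 of its arrays did. Net signal means the array's signal minus its median mismatch signal. Where only the brighter array detected a miRNA, its normalised level was set against the lowest normalised level of a detected miRNA on the other array, or the miRNA's own level if higher, and the result is written as at least N-fold. Quantile normalisation ties the brightest probes to fixed ranks, so a log2 ratio of 0.00 for a bright probe states an equal rank, and net signals are given beside such values.

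Counts of miRNAs at 2-fold or more have no test, because 1 array was set against 1. Limma (lmFit and eBayes, two-sided, Benjamini-Hochberg at 0.05) was fitted to a straight line over the dose steps and to the 3 treated arrays against the untreated one. Both fits leave 2 residual degrees of freedom, and their p-values measure the spread around a line or between doses, not between cultures. On simulated data for 80 miRNAs of which 20 were changed, the dose fit recovered 63.75% of slopes of 0.5 log2 per step and 90% of slopes of 1. The fit of treated against untreated arrays recovered 78.75% of shifts of 2 log2.

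Before the data were examined, 14 lists were written: miRNAs described as raised and as lowered by androgen, the let-7, miR-17-92, miR-200, miR-23/27/24, miR-15/16, miR-34 and miR-29/30 groups, the primate chromosome 19 cluster, and markers of blood, muscle, stroma or endothelium, and liver or neurons. A list's median log2 ratio was placed among 10000 random lists of the same size and like mean intensity, which describes these arrays and tests no condition. The rule for named miRNAs, also fixed beforehand, took the 12 in each direction with the same sign at all 3 doses and the largest smallest ratio, up to 4 of the brightest members of each list, the 3 highest and 3 lowest ratios per dose among miRNAs detected on both arrays, up to 10 that passed a limma threshold, and miR-21, miR-141 and miR-125b. Others named were chosen after their values were seen. Names are those of the array's design. Neighbouring miRNA genes, within 10000 bases, were found from a RefSeq gene table of assembly GRCh38.p14, in which 72 of the 79 miRNAs measured at 10 nM were matched. The files name no genome build, so no coordinates are given.

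The alternatives tried were no background correction, median centring, no normalisation, all miRNAs or only those detected on all 4 arrays, the authors' value table, a 1.5-fold threshold, other detection thresholds, other dose scales, a robust intensity-trend prior and leaving out each array. Added after seeing the data were the centred value table, subtraction of each probe's own mismatch signal, 2 other detection rules, and normalisation without the 0.1 nM array. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. The number of arrays limits the precision of every value.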

Results

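Arrays profiled miRNAs in LNCaP prostate adenocarcinoma cells held without androgen and then given 0, 0.1, 1 or 10 nM of the synthetic androgen R1881, with 1 array per dose. The design asks which miRNAs respond to androgen and at which dose. Of 455 human miRNAs, 80 were detected on at least 1 array and 40 on all 4. The untreated array detected 62, and the arrays at 0.1, 1 and 10 nM detected 47, 61 and 74. Signal differed between arrays: over the 40 miRNAs detected throughout, the median ratio of net signal to the untreated array was 0.651 at 0.1 nM, 0.985 at 1 nM and 0.999 at 10 nM. The spike probe Bio B, whose name carries the tag neg, had net signals of 1276, 617, 1214.75 and 2550.5 on the arrays at 0, 0.1, 1 and 10 nM. What gives this probe its signal was not tested. With no replicates, none of the ratios between arrays has an error of its own.

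The brightest probes on the untreated array were those of miR-125b, at a net signal of 16216, and miR-99a, at 9828, followed by let-7a, at 5288; brightness also depends on the probe. These belong to families whose genes lie together in clusters. The net signal of miR-125b was lower on every treated array, at 8525, 11359 and 9499 in order of dose, and its log2 ratio to the untreated array with median centring was -0.17, -0.49 and -0.75. Quantile normalisation, under which miR-125b ranked highest on the arrays at 0, 0.1 and 1 nM and below miR-99a at 10 nM, gave 0.00, 0.00 and -0.44; the last is that exchange of ranks. For let-7a the net signals on the treated arrays were 5342, 5385 and 5975.

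**Figure D1:**
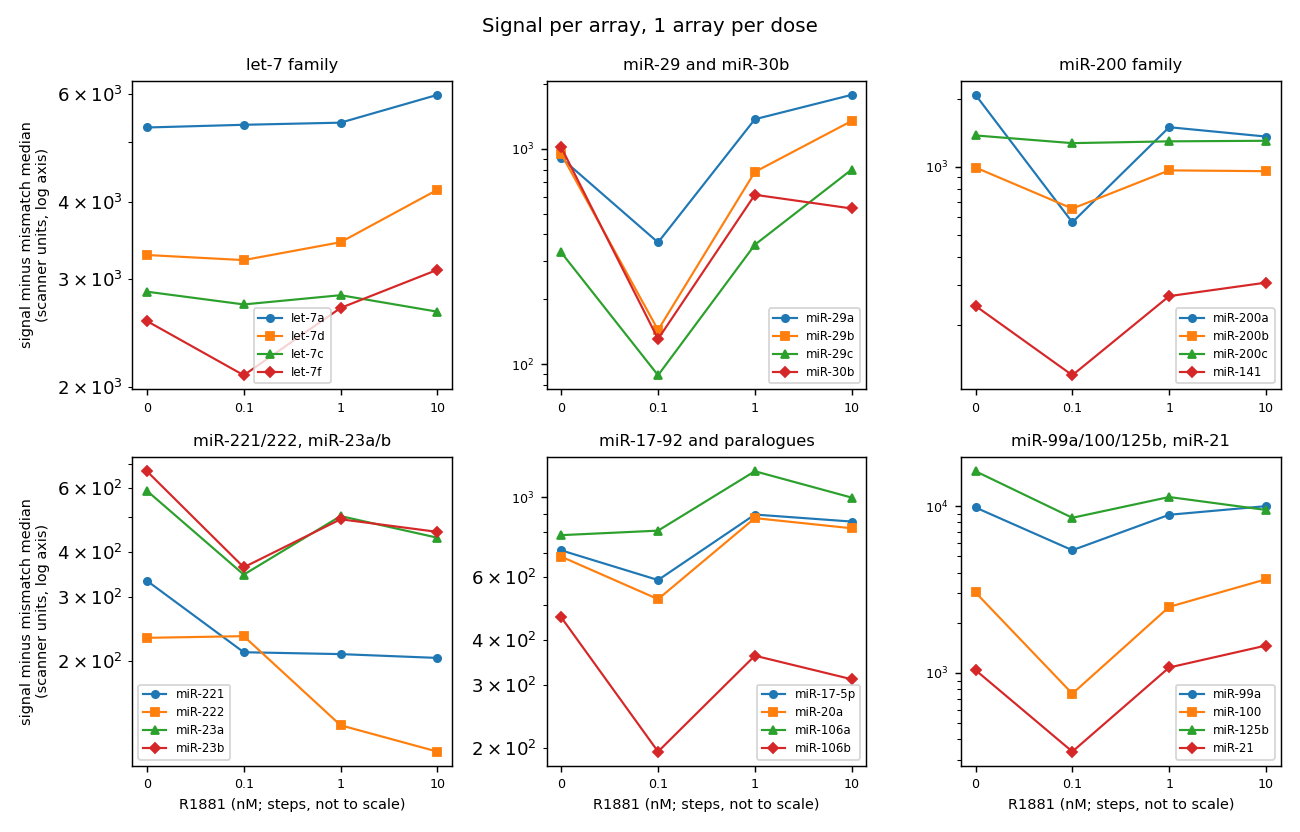
Net signal (array signal minus its median mismatch signal, scanner units, log axis) against R1881 dose in nM as equal steps, for 6 groups of miRNAs; each point is 1 array and has no error bar because there is 1 array per dose, and values are not scaled between arrays. The net signal of miR-29b was 946.25 untreated and 144 at 0.1 nM, while let-7a stayed between 5288 and 5975.

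At 10 nM the highest log2 ratios to untreated cells among miRNAs detected on both arrays were those of miR-601 at 0.93, miR-29a at 0.80 and miR-29c at 0.74. The mismatch probe of miR-601 stood at 1.02, on signals not above background. MiR-29b, of the miR-29 family, whose known targets include collagen mRNAs, stood at 0.13. The lowest values at 10 nM among miRNAs detected on both arrays were those of miR-30b at -1.08, miR-425-5p at -0.89 and miR-221 at -0.73. MiR-221, known to target the cell cycle inhibitor p27, had net signals of 333 untreated and 204 at 10 nM. MiR-23a and miR-23b, of related clusters, gave -0.54 and -0.66 at 10 nM. MiR-16, of a family that targets cyclins and BCL2, was 1.47-fold the untreated level, while its relatives miR-15a, miR-15b and miR-195 had log2 ratios of -0.41, -0.14 and -0.26; that of miR-15b was 0.02 with median centring. In the miR-200 family, which marks epithelial cells, miR-200a, miR-200b and miR-200c stood at -0.58, -0.33 and -0.29, and miR-141 at 0.05.

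Of 79 miRNAs detected on either array at 10 nM, 4 differed by 2-fold or more, 3 higher and 1 lower. The higher ones were miR-214, miR-494 and miR-568, none of which was detected in untreated cells, and the lower one was miR-30b; miR-494 and miR-568 were chosen after their values were seen. MiR-494 was at least 2.62-fold higher, miR-214 at least 1.53-fold and miR-568 at least 1.12-fold. Median centring, which moved the median log2 ratio of the 80 miRNAs by 0.18, gave 7 higher and 0 lower, and no background correction gave 1 and 0. The mismatch probe of miR-568 was higher at 10 nM as well, with a log2 ratio of 2.06.

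At 1 nM the values lay closer to the untreated array, with an SD of log2 ratios over miRNAs of 0.33 against 0.52 at 10 nM. Of 66 miRNAs, 1, miR-494, reached 2-fold, at least 2.03-fold higher; without background correction 0 did, and miR-494 stood at 0.74. Among miRNAs detected on both arrays, the highest log2 ratios at 1 nM were those of miR-601 at 0.76, miR-16 at 0.69 and miR-106a at 0.50. The lowest were miR-638 at -0.90, miR-30b at -0.66 and miR-425-5p at -0.45. The mismatch probe of miR-638 had a net signal of 201.25 at 1 nM, beside 188 for its match probe, so that signal is not specific. MiR-29a was at 0.43, and miR-221 and miR-23b were at -0.43 and -0.42.

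At 0.1 nM, 5 of 65 miRNAs were lower by 2-fold or more and 0 were higher. MiR-30b was at least 3.40-fold lower, miR-29b at least 3.11-fold, miR-29c at least 1.29-fold and miR-19b at least 1.15-fold, since these were not detected on that array. These bounds hold under quantile normalisation: the log2 ratios of miR-30b and miR-29b were -1.60 and -1.42 with median centring, and -1.42 and -1.25 without background correction. MiR-100, detected on both, was 2.28-fold lower, with net signals of 3038 and 750.75. Among miRNAs detected on both arrays, miR-21 and miR-200a followed, at log2 ratios of -0.88 and -0.65, and the highest were let-7e at 0.83, miR-106a at 0.77 and miR-93 at 0.75; the mouse probe of miR-106a stood at -0.46, and without normalisation the human probe stood at 0.00 and the median of all 80 miRNAs at -0.45. Of the 5, miR-100 alone was detected on all 4 arrays.

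**Figure D2:**
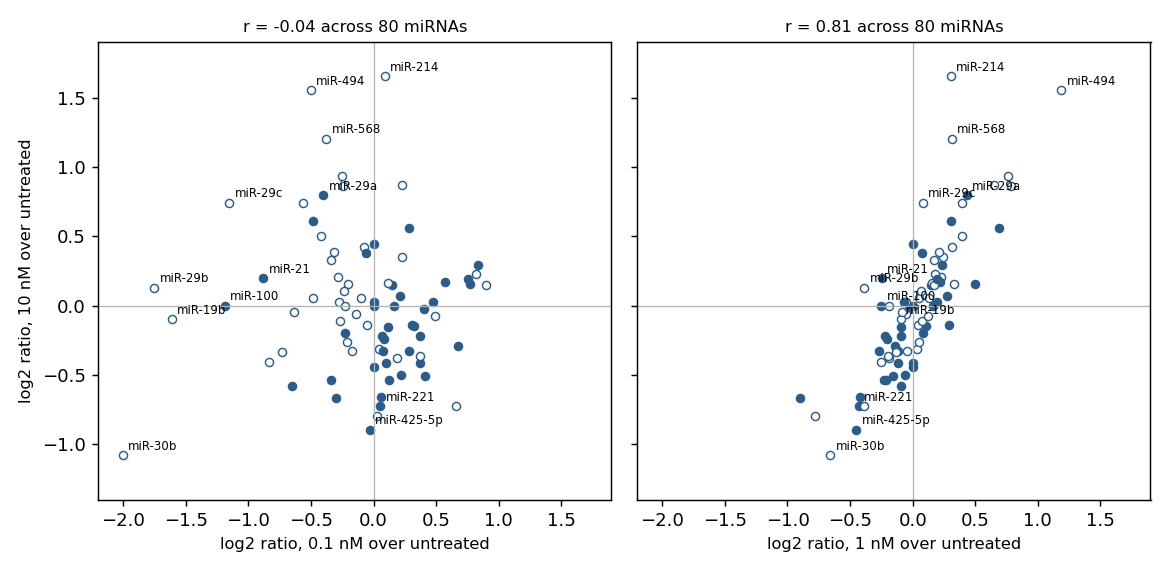
Log2 ratios to the untreated array at 10 nM (vertical) against 0.1 nM (left) and 1 nM (right); each point is 1 of 80 miRNAs, filled where all 4 arrays detected it and open otherwise. The correlation across miRNAs is -0.04 for 0.1 with 10 nM and 0.81 for 1 with 10 nM, and all ratios share 1 untreated array.

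The ratios at 1 and 10 nM were alike across the 80 miRNAs (Pearson r = 0.81, Spearman rho = 0.82), and those at 0.1 nM were like neither, with r = 0.18 against 1 nM and -0.04 against 10 nM. MiRNAs are not independent replicates. The shared untreated array alone gave r = 0.48 for each pair in simulations of unchanged arrays, with ranges of 0.138 to 0.754 for 1 with 10 nM, below the observed value, and 0.126 to 0.742 for 0.1 with 10 nM, above it. The covariance was 0.14 for 1 with 10 nM against a simulated 0.12. It could not be split, since 1 untreated array exists. Between 1 and 10 nM, 2 miRNAs were at 1.5-fold or more higher in both and 3 were lower in both. Unchanged arrays that share the untreated one gave 2.16 and 2.12 in simulations, and independent lists would give 0.273 and 0.318. The simulated lists of higher miRNAs held 5.249 at 1 nM and 5.336 at 10 nM, where the arrays gave 3 and 6. At 1 nM the simulated list was thus longer than the observed one. The simulated overlap therefore cannot decide whether the shared untreated array accounts for the observed overlap.

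Lists fixed beforehand were compared by their median log2 ratio. Of 12 miRNAs described as raised by androgen, 8 were measured; 2 members, miR-21 and miR-141, were also reported by the study's own authors, so the list is not independent evidence for them. At 10 nM, 6 of the 8 were higher and the median was 0.16, at percentile 91.98 of random lists; over the 4 members detected on all arrays the median was -0.17. At 0.1 nM, 1 of the 8 was higher and the median was -0.52, at percentile 0.89. MiR-21, an abundant miRNA in many tumours, had net signals of 1040, 337.25, 1078 and 1459.5 from 0 to 10 nM and log2 ratios of -0.88, -0.25 and 0.20; at 1 nM its sign turned with median centring, to 0.06. MiR-141 had net signals of 243.5, 120.5, 269 and 308.5. Of the 5 described as lowered by androgen, the median was 0.05, -0.25 and -0.15 at 0.1, 1 and 10 nM. The value at 1 nM lay at percentile 1.28, and at 5.30 with median centring. MiR-99a, the brightest of them, had net signals of 9828, 5447, 8888 and 10013.

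The miR-29 and miR-30 families had 6 of 6 measured members lower at 0.1 nM, with a median of -0.78 at percentile 0.325 (-0.31 at percentile 9.545 over the 2 members detected on all arrays), and medians of 0.07 and 0.12 at 1 and 10 nM. At 10 nM, 4 of the 6 were higher and 2 lower, at percentile 80.4. The miR-17-92 group, known for promoting proliferation, had 7 of 9 higher at 0.1 nM, with a median of 0.37 at percentile 98.5. That percentile was 94.7 with median centring, and without normalisation its median was -0.39. Its members miR-17-5p and miR-20a stood at 0.17 and 0.03 at 10 nM, and miR-106b at -0.54. The let-7 family had 8 measured members with medians of 0.24, 0.12 and 0.00 in order of dose; the percentile at 0.1 nM was 81.975, and 98.77 with median centring. Medians in that order were -0.20, -0.12 and -0.31 for 4 of the miR-200 family, -0.21, 0.04 and -0.26 for 5 of the miR-15/16 family, and 0.09, -0.31 and -0.60 for 2 of the miR-23/27/24 clusters. Of the p53-responsive miR-34 family, miR-34a was detected on all arrays but that at 0.1 nM, at -0.09 and -0.04 at 1 and 10 nM, the latter of which was 0.11 with median centring. Scaling turned the sign of these medians at 0.1 nM: median centring gave 0.08 for the miR-200 and 0.18 for the miR-15/16 family, and no normalisation gave -0.14 for the let-7 family and -0.74 for the miR-23/27/24 clusters. In all, 4 of 24 list medians lay in the outer 2.5% of random lists at either end, where 1.2 were expected, and 3 of the 4 were at 0.1 nM. These medians are not independent, so the excess has no test. MiR-29a and miR-29b are in both the list raised by androgen and the miR-29 and miR-30 families, and all doses share the untreated array. Members of 1 family may also vary together, which the random lists do not copy. With each probe's own mismatch signal subtracted, the percentiles at 0.1 nM were 3.12 for the list raised by androgen, 11.6 for the miR-29 and miR-30 families, 79.22 for the miR-17-92 group and 99.44 for the let-7 family.

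Markers of other cell types were not detected for blood, muscle, and liver or neurons, nor was any of the 37 placental chromosome 19 miRNAs. Of the 5 stromal and endothelial markers, miR-214 was detected, on the 10 nM array alone, with net signals of 11.25, 43.5, 36.75 and 377.

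No miRNA passed the limma threshold for a trend over the doses. With limma, 7 of 80 had an unadjusted p under 0.05, 3 higher and 4 lower with dose, where 4 were expected by chance, and the lowest adjusted p was 0.498. Among miRNAs detected on all 4 arrays, the slopes per dose step were -0.31 ± 0.08 (SE) for miR-425-5p, -0.27 ± 0.08 for miR-221 and -0.25 ± 0.08 for miR-23b. Subtracting each probe's own mismatch signal, a setting added after seeing the data, gave 2 calls, miR-494 higher and miR-638 lower with dose, at a limma adjusted p of 0.0396. The net signal of miR-638 was 188 against 201.25 for its mismatch probe at 1 nM and 300.25 against 280.75 at 10 nM, so its slope, -1.03 against -0.26 in the main fit, rests on the floor of that subtraction. MiR-214 passed the trend fit when adjusted over the list alone, as the single measured member of its list, though it was not above background on 3 of the 4 arrays. No member of any other list passed over its list or over all 80.

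For the 3 treated arrays against the untreated one, limma made 0 calls, with a lowest adjusted p of 0.963 and 0 miRNAs at an unadjusted p under 0.05. Of the 80 miRNAs, 25 had the same sign at the 3 doses, 14 higher and 11 lower, or 31.25%, where chance gives 50% with a shared untreated array. MiR-16 headed those higher, at log2 ratios of 0.28, 0.69 and 0.56, and without normalisation it was at -0.51 at 0.1 nM. MiR-30b headed those lower, at -0.66 and -1.08 at 1 and 10 nM and not detected at 0.1 nM. It was followed by miR-638 at -0.30, -0.90 and -0.67, whose mismatch probe was no dimmer than its match probe at 1 nM.

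**Figure D3:**
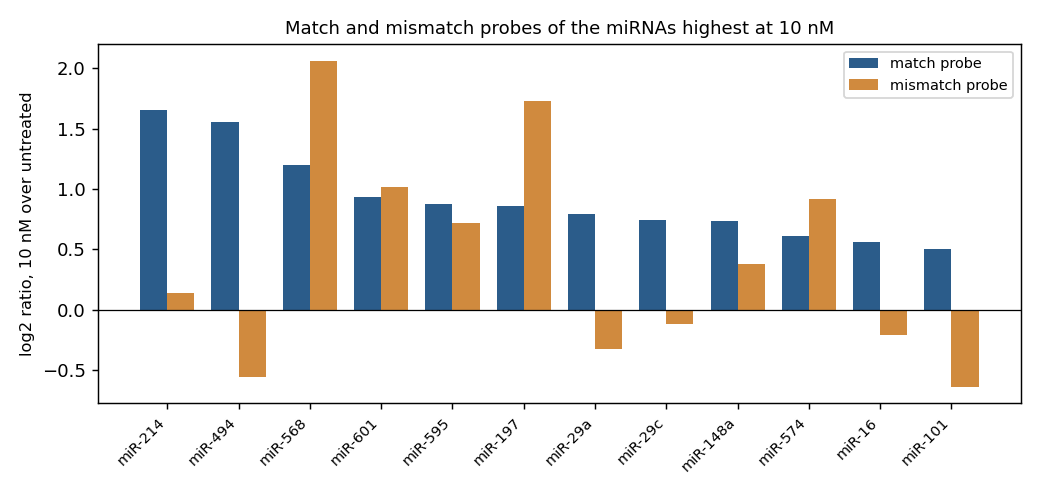
Log2 ratio of the 10 nM array to the untreated array for the 12 miRNAs at 0.5 or more, for the match probe (blue bars) and the same probe with mismatched bases (orange bars), 1 array per dose and no error bars. The mismatch probe of miR-568 stands at 2.06 and that of miR-197 at 1.73; the 10 nM array detected 3 of the 12 mismatch probes, and the bars of the others rest on signals not above background.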

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

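The tests of the order of the arrays and of ratios that share no array were planned; the tests of probe pairs, exchanged labels, an effect at 0.1 nM, mismatch probes and the miRNAs highest at 10 nM were chosen only after the results were seen.

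Signals appeared on treated arrays in probes that the comparisons do not use and that the untreated array did not detect. Among mouse probes, the log2 ratio to the untreated array was 1.34 for let-7d* and 1.58 for miR-692 at 0.1 nM, and 1.75 for miR-494, 1.34 for miR-709 and 2.01 for miR-713 at 10 nM. The human and mouse probes of miR-494 gave 1.55 and 1.75 at 10 nM. Among mismatch probes of human miRNAs, that of miR-197 stood at 1.73 at 10 nM, and that of miR-568 at 1.61 at 1 nM and 2.06 at 10 nM. The array at 10 nM detected 16 mismatch probes and 9 viral or worm probes, against 4 and 2 on the untreated array.

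Several miRNAs, among them miR-30b, miR-29b, miR-29c, miR-19b and miR-100, were lower on the 0.1 nM array than on any other. Probes of different species for 1 miRNA name lay further apart at 0.1 nM than at 10 nM in 9 of 11 pairs that were not tied (exact sign test, two-sided, p = 0.0654; 1 human probe is in 2 pairs), with median absolute differences of 0.39 and 0.26, so a probe-dependent fault of hybridisation may contribute and is not shown. Read in the order 0.1, 0, 1 and 10 nM, 30 miRNAs had steadily rising or falling levels, against 5 in the labelled order (15 against 1 of the 40 detected on all arrays), which is what exchanged labels of the untreated and 0.1 nM arrays would give; a technical scale on which these arrays lie in that order would give it too. In that order the arrays detected 3, 4, 7 and 16 mismatch probes and 18, 22, 23 and 36 probes of other species, which goes with such a scale. The brightest glycine tRNA probe goes with it too, at 173, 299, 341 and 665, while the dimmer glycine tRNA probes do not. The Bio B and Bio C spikes ran 0.1, 1, 0 and 10 nM from low to high, an order with 7 steady miRNAs, which does not go with it. On the 1 nM and untreated arrays Bio B stood at 1214.75 and 1276, and Bio C at 1235.5 and 1563.25. An effect of 0.1 nM R1881 stays open, since 1 pair of probes had a human probe at or below -0.5, with a difference of 0.306. That pair is miR-494, whose human probe had net signals of 116.25 untreated and 71.5 at 0.1 nM. Neither was above background, so its difference says little. A lower overall signal on that array was tried as well and left undecided: the SD of its ratios was 1.79 times that at 1 nM, and 1.26 times without the 5 lowest miRNAs.

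The labelled order gave 5 miRNAs with steady levels, miR-181b, miR-193b, miR-214, miR-595 and miR-425-5p, where 6.67 were expected of random orders; 4 of these 5, all but miR-425-5p, were detected on 1 array, so their order rests on signals not above background. Of the 12 orders of 4 arrays, 5 gave at least as many, and the highest other gave 30; 12 orders are too few for a share under 0.05. The 30 points to a structure of the arrays other than the labelled dose order, which exchanged labels would give as well.

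Of the 12 miRNAs at 0.5 log2 or more at 10 nM, the match probes had a median of 0.83 and their mismatch probes 0.257, with quartiles of -0.24 and 0.94. Non-specific signal may account for miR-568, miR-197 and miR-595, whose mismatch probes the 10 nM array detected and whose mismatch net signals were higher than untreated by 562.75, 262.75 and 125.25, beside 225.75, 158.75 and 150.75 for the match probes. In the other 9, a division made after the values were seen, no mismatch probe was detected. Their mismatch net signals were higher by a median of 7.75 (at most 137.75), beside 471 for the match probes. In each of the 9 the net signal rose more in the match probe than in its mismatch probe. The division itself keeps the mismatch values small, so it cannot exclude shared signal. The mismatch log2 ratios of miR-601 and miR-574, 1.02 and 0.92, were above the match probes' 0.93 and 0.61, and those of the rest were below. Other RNAs that only the match probe binds stay possible, and over all 12 the test stays undecided. An effect of R1881 needs the same miRNAs to be higher at 1 nM than at 0.1 nM, arrays that did not choose them, and 8 of the 8 detected at either dose were. That decides nothing, since 5 of the 8 were detected at 1 nM and not at 0.1 nM, which nearly fixes the outcome: 14 of the 15 other miRNAs so detected were higher at 1 nM too. The 3 detected at both doses were all higher at 1 nM, against 7 of 38 others, but 3 are few, and the order of the arrays given for the 0.1 nM pattern predicts it as well, so an effect of R1881 stays open; 2 earlier forms of this test, each with 12 of 12, were set aside because they shared the untreated array or read signals not above background.

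The ratios at 1 and 10 nM were alike, with r = 0.81. If the shared untreated array were the whole cause, ratios that share no array would show no likeness. The ratio of 1 nM to untreated and that of 10 nM to 0.1 nM correlated at 0.413 across 80 miRNAs, and the other pairing at 0.502, which argues against that array as the whole cause. On the 40 miRNAs detected on all arrays the smaller value was 0.265, under the planned bound. An effect of androgen common to both doses and a technical order of the arrays both stay open, the latter with the 30 steady miRNAs of the order 0.1, 0, 1 and 10 nM.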

How the results depend on the processing

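Of the alternatives below, those using the centred value table, each probe's own mismatch signal, the 1.5 times rule, viral controls or normalisation without the 0.1 nM array were chosen after seeing the data. Of the named miRNAs with a 2-fold ratio, miR-568 alone changed sign, to -0.10 at 10 nM with its own mismatch signal subtracted. Its net signal was below that of its mismatch probe on both arrays, 11.25 against 15 untreated and 237 against 577.75 at 10 nM. Both levels were therefore set to the floor of 50 of that subtraction. The -0.10 comes from the centring of the arrays, and no direction was measured. The counts at 2-fold, 5, 1 and 4 at 0.1, 1 and 10 nM, moved most, and the cause was not tested unless stated. They were 3, 0 and 1 without background correction, 11, 2 and 7 without normalisation, 8, 7 and 11 with each probe's own mismatch signal subtracted, and 17, 6 and 17 at 1.5-fold. Median centring gave 2 at 1 nM and 7 at 10 nM; all human miRNAs gave 7 at 10 nM, where more were counted. Only miRNAs detected on all 4 arrays gave 1, 0 and 0, where fewer were counted. The value table as deposited gave 2 at 10 nM, and centred it gave 3 at 0.1 nM and 2 at 1 nM. Leaving out the 0.1 nM array gave 2 at 1 nM and 5 at 10 nM. At 10 nM the split was 3 higher and 1 lower, 7 and 0 with median centring, 7 and 4 with own mismatch signals, and 0 and 3 with the centred value table; at 0.1 nM it was 0 and 5, 2 and 4 with median centring, and 2 and 6 with own mismatch signals. Medians of all 80 log2 ratios shifted to 0.30 at 0.1 nM with median centring and to -0.45 without normalisation.

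The trend fit made 0 calls under each alternative except subtraction of own mismatch signals, which made 2. Its lowest limma adjusted p ranged from 0.0396 to 0.742 over other settings with all 4 arrays. It was 0.061 without the 0.1 nM array, where 20 miRNAs had an unadjusted p under 0.05, and 0.162 without the untreated array, also with 20. Without the 1 nM array it was 0.990, with 1 such miRNA, and without the 10 nM array 0.996, with 0. Treated against untreated arrays gave 0 calls throughout, with 0 to 17 miRNAs at an unadjusted p under 0.05. Of the list medians, 4 lay outside the central range, 1 with miRNAs detected on all arrays and 1 with own mismatch signals. The correlation of 1 with 10 nM stayed between 0.7516 and 0.8257. That of 0.1 with 10 nM was 0.2063 with median centring and without normalisation, and 0.3308 with own mismatch signals; that of 0.1 with 1 nM was 0.3982 with the value table as deposited and centred. Detection at 5 scaled deviations left 52 miRNAs of 80. Of 145 ratios of named miRNAs, 13 changed sign with median centring and 23 without normalisation, of which 0 and 3 were at 1.5-fold or more. The median over spots was not run, since the files used here give means. No paired analysis was possible because each group has 1 array. Signal over background limits miRNAs such as miR-214, miR-568 and miR-595, which 1 array detected.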

Other observations

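The test of neighbouring miRNA genes was planned for pairs of different families, with a shuffle over all measured miRNAs. That shuffle was run with pairs of the same family included. Leaving most of those pairs out, shuffling among the paired miRNAs and reading other doses came after its result was seen.

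The miRNAs of this paragraph were chosen after their values were seen. MiR-222, which shares a cluster and a seed with miR-221, stood at -0.72 at 10 nM beside -0.73 for miR-221. MiR-26a and miR-26b, relatives that share a seed, were at -0.51 and -0.50. MiR-191, a neighbour of miR-425-5p, was at -0.42 beside -0.89. MiR-148a, described as raised by androgen, was at 0.74 at 10 nM and was not detected at 0.1 nM. Neighbours also went apart, as miR-106b at -0.54 and miR-93 at 0.19 did at 10 nM. MiR-16 stood at 0.56 beside miR-15a at -0.41 and miR-15b at -0.14. It is a neighbour of both, and its probe cannot tell the 2 places apart, so this contrast does not show that members of 1 cluster differed.

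The small U6 RNA probe gave net signals of -9.5, -10.5, -22.75 and -35.0 from 0 to 10 nM, and was not used to scale the arrays. The brightest glycine tRNA probe gave 299, 173, 341 and 665 in the same order. A dimmer probe named for the same stretch of that tRNA gave 26, 54.25, 25.75 and 112.75.

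A hypothesis was that miRNAs transcribed from neighbouring genes have like ratios, as they may where 1 transcript holds both. Within 21 pairs of neighbours among 28 miRNAs the mean absolute difference of the log2 ratio at 10 nM was 0.32, at percentile 0.55 of shuffles over all measured miRNAs. The planned bound of the lowest 5% was written for pairs of different families, and these 21 include pairs of 1 family, such as miR-221 and miR-222. Shuffled among the paired miRNAs, which are brighter than the rest, the mean difference of the 21 pairs lay at percentile 8.75. With most pairs of 1 seed family left out, as their probes may cross-hybridise, 14 pairs lay at 4.08, under that bound in a shuffle chosen later. The 14 still held miR-221 and miR-222, which share a seed and differed by 0.0025 at 10 nM. No percentile without that pair was computed, so 4.08 is not a value for different families alone. The same 14 pairs lay at percentile 42.0 at 1 nM and at 99.65 at 0.1 nM, where neighbours were further apart than shuffled pairs, with a mean difference of 1.06 against 0.65. The value at 0.1 nM rests in part on miR-19b, at a log2 ratio of -1.61. That array did not detect it, at a net signal of 27.75. MiR-19b is paired with miR-17-5p, miR-20a, miR-20b and miR-106a, which stood at 0.57, 0.47, 0.21 and 0.77 at 0.1 nM. That percentile therefore cannot be held against a shared transcript, and the hypothesis stays undecided.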
